A study of Brassica rapa with 9 samples.

How the data were processed

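RNA-seq was carried out on whole 2-week-old Brassica rapa seedlings (cultivar Chiifu) grown on MS medium with 0.5% sucrose, without heat treatment and in long days as the labels abbreviate them (LD). The 9 libraries fall into 3 genotypes of 3 replicates each, assigned from the sample titles: non-transgenic plants (NT), plants carrying Arabidopsis thaliana phytochrome B (AtPHYB), and plants carrying a phytochrome B with glycine replaced by glutamate at residue 564 (G564E). The labels do not say whether replicates were separate plants, pools or lines, so p-values measure the spread between these libraries, which may be partly technical. Each library was made from DNase-treated total RNA with a stranded mRNA kit and sequenced on a NovaSeq instrument, per the labels' protocols.

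The deposited values are raw counts of reads per gene, 1 library per file, as the whole numbers in the files show. Per the submitters' processing notes, reads passed through FastQC 0.11.8, Trimmomatic 0.39, TopHat2 and HTSeq, and edgeR was used afterwards. The settings of these tools, the genome build, the annotation and the strand option of the counting are not given in the sources used here. All 9 files list the same 41020 gene IDs, of which 5057 had no read in any library. The files hold IDs only and do not pair them with gene names. A gene table of the CAAS_Brap_v3.01 assembly with 51589 genes was compared with these IDs, and 1 ID matched (Bra000116, listed there as SWEET9). No coordinates, gene lengths or sequences of the annotation behind the counts were used. Read sharing between the duplicated gene copies common in Brassica could not be examined. The transgene and the resident phytochrome B genes could not be tied to an ID, so no check of the genotype labels by the introduced gene was made.

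Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr at its default settings (27967 genes), libraries were scaled by TMM, and a quasi-likelihood model with a mean per genotype was fitted to all 9 libraries, so that the 3 genotypes share one estimate of the spread. The tests were 2-sided, with Benjamini-Hochberg adjustment over all tested genes within each comparison, and a gene was called at an adjusted p under 0.05. The contrasts tested were 3: AtPHYB minus NT, G564E minus NT and G564E minus AtPHYB. Standard errors of log2 fold changes were taken as the log2 fold change divided by the square root of its F statistic. CPM values were computed with edgeR's cpm function on TMM-scaled library sizes. Where a group had no read at an ID, the fold was computed against a floor of 3 counts over that group's 3 libraries, and given as a lower bound. Where a group had 1 to 3 reads in all, the ratio of summed counts was given with an exact 95% interval. These intervals and floors cover counting error only, because PCR copies are not independent molecules.

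The rule for named IDs was set before the data were examined, as were the contrasts, the test and the alternatives, except where the closing section says otherwise. With no names, the rule allowed the 2 highest and 2 lowest log2 fold changes per contrast among IDs with an adjusted p under 0.05, a mean of at least 5 CPM over the 9 libraries, and all 3 libraries of one genotype above all 3 of the other. The numbers of IDs meeting these conditions were 40, 5665 and 7193 in the order of the contrasts above. A total of 33 gene lists (light signalling, photosynthesis, hormones, defence, tissue markers and others) had also been fixed, by names, symbols or protein motifs. Without names or sequences none of them could be filled, and no list was tested. Genes were instead grouped by abundance, into 4 classes of equal size by the mean CPM over all 9 libraries and as the 100 most abundant genes. Rankings by the mean of the genotypes compared and by single genotypes were added after seeing the data.

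The comparisons against NT share the 3 NT libraries. Their overlap and correlation were set beside 20 simulations of 9 libraries with no genotype effect, drawn from negative binomial distributions with the real means, library sizes and dispersions. Each simulated library was drawn independently of the others. Splitting the controls was not possible with at least 2 libraries in each part. The model was tested on simulated data with 200 genes changed. It recovered 10% of 2-fold and 79% of 4-fold changes for AtPHYB minus NT (27535 genes), 14% and 72% for G564E minus NT (27521 genes), and 4% and 69% for G564E minus AtPHYB (27523 genes), with 2, 4 and 2 false calls.

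The labels number the replicates 1 to 3 in every genotype. Deviations from the group means correlated at 0.41, 0.31 and 0.12 between AtPHYB and G564E libraries of the same number. The numbers may therefore pair these libraries, but this was not tested, and no label says what a number marks. The reported tests leave this possible pairing out, and fits with the replicate number as a block are given as alternatives. Between NT and the other genotypes the same correlations ran from -0.17 to 0.085, so there the libraries shared only a number. Library pairs within a genotype differed by far more than sampling noise, with a chi-square per degree of freedom of 10.8 or more in each of the 9 pairs, and none was treated as a duplicate. Alternatives covered scaling (RLE size factors, library size alone), the low-count filter, DESeq2 1.42.0, limma-voom (limma 3.58.1), fits to the compared genotypes alone, stricter thresholds, the replicate block and each library left out in turn.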

Results

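The series asked how transgenic Kimchi cabbage carrying Arabidopsis phytochrome B differs in its transcriptome from non-transgenic plants. Phytochrome B is a red and far-red light receptor of plants. One transgenic genotype carried the unmodified receptor (AtPHYB) and the other a form with glutamate in place of glycine at residue 564 (G564E). Non-transgenic plants (NT) were the control, with 3 libraries per genotype. Total gene counts were 19450892 ± 1962255 in NT, 18916690 ± 918454 in AtPHYB and 17377621 ± 1832757 in G564E (mean ± SD, n = 3 each), and ranged from 15262884 to 20998541 per library. At least 1 read was counted at 31780 ± 141 gene IDs in NT, 31512 ± 549 in AtPHYB and 32269 ± 560 in G564E (SD, n = 3 each). The IDs carry no gene names, so genes are given by ID, by abundance and by response. The 1 ID with a name, Bra000116 (SWEET9, a sugar transporter of the SWEET family), had 2 reads in G564E replicate 2 and 0 in the other libraries, and was not tested.

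The G564E libraries were separated from the rest along the first principal component, which held 54.2% of the variance of log2 CPM. Spearman correlations between G564E and other libraries lay between 0.863 and 0.900, against 0.947 to 0.978 between NT and AtPHYB libraries. G564E replicate 1 stood apart from its own group, with correlations of 0.915 and 0.912 to replicates 2 and 3, which correlated with each other at 0.985. NT replicate 3 correlated more closely with AtPHYB replicate 3 (0.978) than with NT replicates 1 (0.967) and 2 (0.963). At 56 genes every library was either at 5 CPM or more or at 0.2 CPM or less, with both states present. NT replicate 3 differed in this on/off state from NT replicates 1 and 2 at 43 and 40 of these genes, and from the AtPHYB libraries at 7 to 9. AtPHYB libraries differed from one another at 3 to 6 of them, and NT replicates 1 and 2 at 11.

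**Figure D1:**
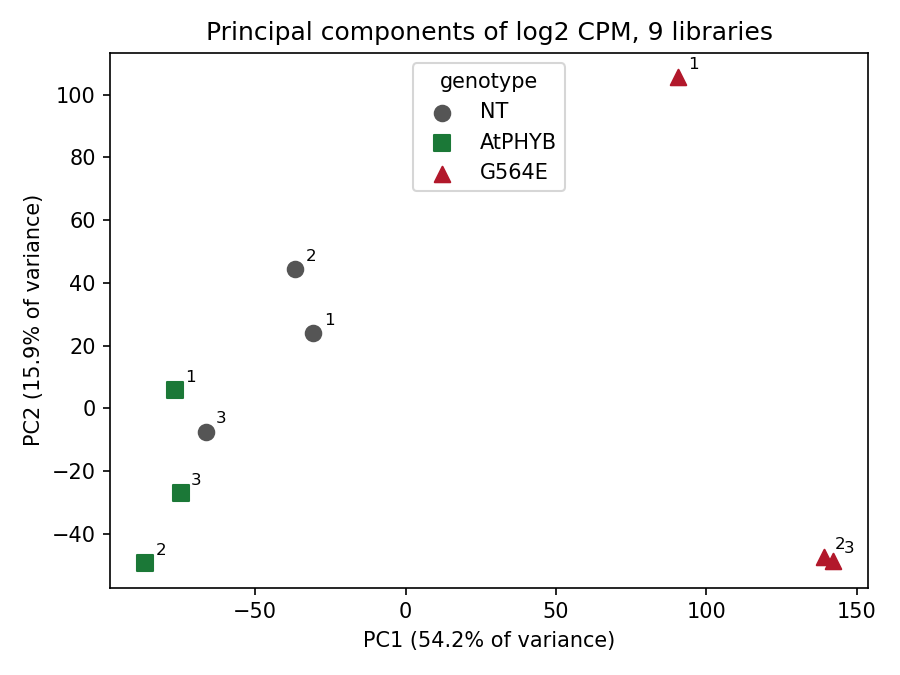
Principal components 1 (54.2% of the variance) and 2 (15.9%) of log2 CPM for the 9 libraries; each point is a library, coloured by genotype and marked with its replicate number. The G564E libraries lie apart on the first component, G564E replicate 1 lies apart on the second, and NT replicate 3 lies between the other NT libraries and the AtPHYB libraries on the first component.

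The first comparison asked how plants carrying the unmodified receptor differed from NT. The plant line and any difference in growth or handling follow the genotype, so none of the comparisons isolates the receptor. In AtPHYB, 29 genes were higher and 24 lower than in NT among 27967 tested, or 0.19% of them (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The median absolute log2 fold change of the called genes was 2.49, and 47 of the 53 changed at least 2-fold. Bra024707 rose from 1 read in all 3 NT libraries to 50.7 ± 3.64 CPM in AtPHYB (SD, n = 3), a ratio of 2810 with an exact 95% counting interval of 503 to 111000 (edgeR adjusted p = 7.57e-06). In G564E, Bra024707 stood at 0.0982 ± 0.0127 CPM, so a high level was seen in AtPHYB libraries alone. Bra019635 rose from 2 reads in NT to 26.4 ± 10.5 CPM in AtPHYB, a ratio of 723 with an exact 95% counting interval of 200 to 5980 (edgeR adjusted p = 0.00926), and had no read in G564E. Bra024707 and Bra019635 are both on/off genes, so a difference between the plants other than the receptor stays open for them. Bra024871 fell from 35.3 ± 11.9 CPM in NT to 1.99 ± 0.347 CPM in AtPHYB, a log2 fold change of -4.15 with a standard error of 0.31 (edgeR adjusted p = 0.00295). In G564E, Bra024871 was at 38.8 ± 6.79 CPM. Bra027957 fell from 14.3 ± 1.99 to 0.854 ± 0.648 CPM, a log2 fold change of -4.02 with a standard error of 0.47 (edgeR adjusted p = 0.0205), and was at 8.11 ± 1.66 CPM in G564E.

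The called genes of AtPHYB were spread over the abundance range, with 11, 12, 18 and 12 of them in the 4 equal abundance classes from the least to the most abundant genes, and none of the 100 most abundant genes was called. Without an adjustment, 3793 of the 27967 genes had a p under 0.05 (edgeR). At 26.7% of the tested genes the AtPHYB and NT libraries did not overlap, against 10% by chance, so smaller differences may have gone uncalled. Genes vary together between libraries, so this excess is not a count of changed genes. The count of 53 changed by more than 1.5 times when any single library was left out. It was 6 without NT replicate 1, 7 without NT replicate 2 and 783 without NT replicate 3. It was 12, 15 and 9 without AtPHYB replicates 1, 2 and 3, and 343, 24 and 28 without G564E replicates 1, 2 and 3, which enter through the shared estimate of the spread. Bra024707 and Bra024871 kept an adjusted p under 0.05 in each of these fits, whereas Bra019635 had an adjusted p of 0.062 and 0.0724 without NT replicates 1 and 2, and Bra027957 reached 0.133 without AtPHYB replicate 3, 0.107 without NT replicate 1 and 0.0734 without NT replicate 2 (edgeR). DESeq2 called 961 genes, a fit to the 6 libraries of these genotypes called 199, and 6 genes had an adjusted p under 0.01 (edgeR). Scaling by library size alone gave 25 higher and 33 lower genes, 43.1% higher against 54.7% with TMM, and moved the median log2 fold change of all genes to -0.11.

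The second comparison asked how plants carrying the G564E form differed from NT. In G564E, 3847 genes were higher and 3698 lower than in NT, or 27.0% of the 27967 tested (edgeR quasi-likelihood test, adjusted p under 0.05), and 2477 and 1976 of them changed at least 2-fold. Of the 100 most abundant genes over all 9 libraries, 67 were lower, 2 were higher and 31 were not called, with a median log2 fold change of -1.51 (quartiles -2.74 and -0.712). This split depends on the ranking, because 6 of the 9 libraries are not G564E and a ranking over all of them favours genes that are lower in G564E. Ranked by the mean of NT and G564E, 59 were lower, 3 higher and 38 not called, with a median of -1.18. Ranked by G564E alone, which favours genes that are higher in G564E, 23 were lower, 19 higher and 58 not called, with a median of -0.0744. Ranked by AtPHYB, the genotype not compared here, 76 were lower and 2 higher, with a median of -1.88. AtPHYB libraries correlated more closely with NT than with G564E, so this ranking may also favour genes that are lower in G564E. The 100 genes most abundant in each library itself took 17.9 ± 0.383% of the counts in NT, 19.6 ± 1.51% in AtPHYB and 11.5 ± 0.365% in G564E (SD, n = 3 each). In the most abundant of the 4 classes over all libraries 1763 were lower and 685 higher, and in the least abundant class 359 were lower and 1050 higher. Ranked by the mean of NT and G564E these were 1636 and 799, and 406 and 944; ranked by G564E alone they were 1183 and 1120, and 712 and 649.

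Bra005245 had no read in NT and 88.0 ± 48.0 CPM in G564E, at least 1560-fold higher (edgeR adjusted p = 0.000563), with 0.174 ± 0.194 CPM in AtPHYB. Bra016073 had 3 reads in NT and stood at 0.534, 44.0 and 298 CPM in G564E replicates 1, 2 and 3. Its ratio of summed counts was 2160 with an exact 95% counting interval of 739 to 10500, which leaves out this spread between libraries (edgeR adjusted p = 0.0122), and limma-voom gave it an adjusted p of 0.472. Bra012214 fell from 23.5 ± 15.7 CPM in NT to no read in G564E, at least 476-fold lower (edgeR adjusted p = 0.000883). It was at 29.7 ± 7.74 CPM in AtPHYB. Bra012214 is an on/off gene, so a difference between the plants other than the receptor stays open here too. The highest NT value of Bra012214 was 40.8 CPM in replicate 3, and its log2 fold change moved from -11.8 to -11.1 without that library. Bra035004 fell from 6.44 ± 4.26 CPM in NT to 2 reads in G564E, a ratio of 199 with an exact 95% counting interval of 54.6 to 1650 (edgeR adjusted p = 0.000499). Here too NT replicate 3 was highest, at 11.4 CPM, and the log2 fold change moved from -7.37 to -6.69 without it.

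The count of genes changed in G564E was 7545 with all libraries, 4829 without NT replicate 1, and between 5283 and 10702 without any other library, the highest without G564E replicate 1. Scaling by library size alone gave 7832 higher and 2180 lower genes, 78.2% higher against 51% with TMM. That scaling moved the median log2 fold change of all genes from 0.02 to 0.34, and turned the most abundant class to 1737 higher and 1109 lower, while 66 of the 100 most abundant genes were still lower and 5 higher.

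**Figure D2:**
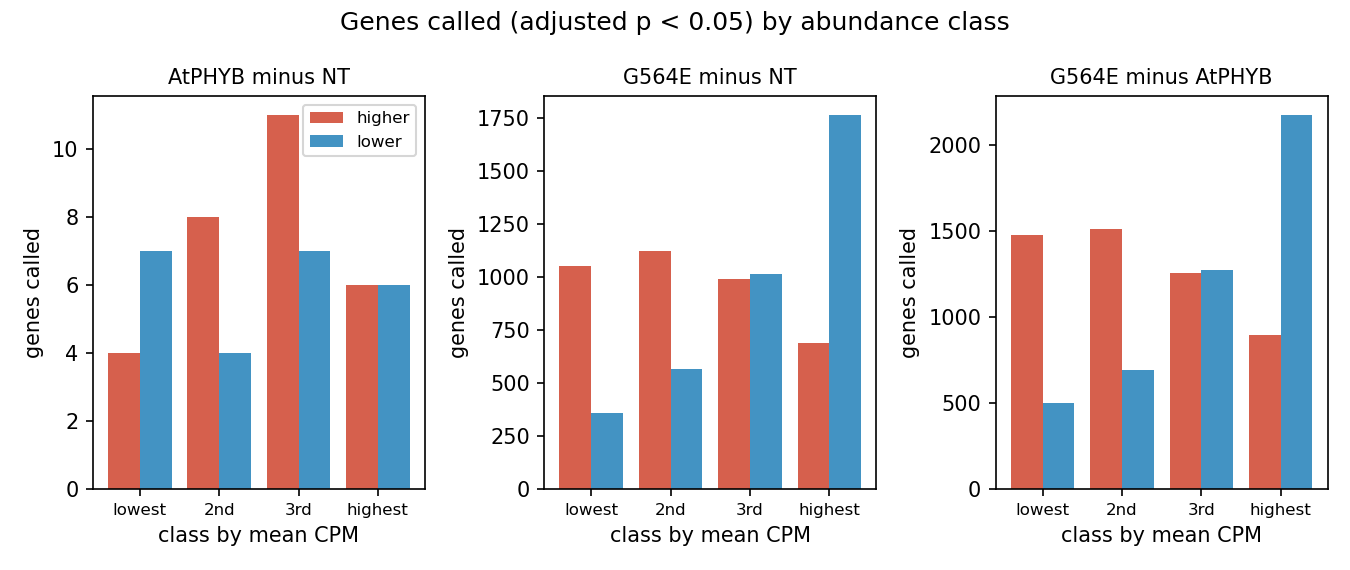
Genes called higher or lower (edgeR, adjusted p under 0.05, TMM scaling) in each comparison, by 4 equal classes of mean CPM over all 9 libraries; bars are counts of genes and each panel has its own axis. In both comparisons of G564E the lower genes outnumber the higher ones in the most abundant class (1763 against 685 relative to NT) and the reverse holds in the least abundant class, a split that depends on the ranking (1948 against 492 in the most abundant class relative to NT when ranked by AtPHYB, and 1183 against 1120 when ranked by G564E alone); with scaling by library size alone the higher genes outnumber the lower ones in the most abundant class as well (1737 against 1109 relative to NT).

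The third comparison set plants carrying the G564E form directly against those carrying the unmodified receptor. G564E had 5140 genes higher and 4637 lower than AtPHYB, or 35.0% of those tested (edgeR quasi-likelihood test, adjusted p under 0.05), and 3351 and 2566 of them changed at least 2-fold. Of the 100 most abundant genes over all libraries 72 were lower and 3 higher in G564E than in AtPHYB, against 71 and 3 when ranked by the mean of these genotypes, 78 and 3 when ranked by NT and 29 and 26 when ranked by G564E alone. NT libraries correlated more closely with AtPHYB than with G564E, so the ranking by NT may also favour genes lower in G564E. Bra010332 had no read in AtPHYB and 8.37, 48.3 and 162 CPM in G564E replicates 1, 2 and 3. It was at least 1230-fold higher on summed counts (edgeR adjusted p = 0.004), and at 0.229 ± 0.217 CPM in NT (SD, n = 3). This bound leaves out the spread between the G564E libraries, and the log2 fold change moved from 13.4 to 12 without G564E replicate 3. The other named IDs of this comparison were on/off genes that also differed within NT. Bra034221 had no read in AtPHYB and 42.2 ± 5.14 CPM in G564E, at least 709-fold higher (edgeR adjusted p = 0.0151), and stood at 18.6, 41 and 0 CPM in NT replicates 1, 2 and 3. Bra030240 had 86.9 ± 5.46 CPM in AtPHYB and no read in G564E, at least 1780-fold lower (edgeR adjusted p = 0.0137), and stood at 53.6, 0 and 71.2 CPM in the NT replicates. Bra009762 had 42.1 ± 4.25 CPM in AtPHYB and no read in G564E, at least 868-fold lower (edgeR adjusted p = 0.0388), and in NT only replicate 3 had reads of it, at 40.6 CPM.

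The count of 9777 fell to 6063 without AtPHYB replicate 2 and to 6366 without AtPHYB replicate 3. Scaling by library size alone gave 10786 higher and 2469 lower genes, 81.4% higher against 52.6% with TMM, and moved the median log2 fold change of all genes from 0.05 to 0.47. Bra010332, Bra034221 and Bra030240 lost their call in limma-voom, with adjusted p of 0.0658, 0.154 and 0.231. Bra009762 lost its call without any AtPHYB library (adjusted p of 0.0736, 0.0855 and 0.0815 without replicates 1, 2 and 3) and without G564E replicates 2 and 3 (0.0739 and 0.077; edgeR).

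**Figure D3:**
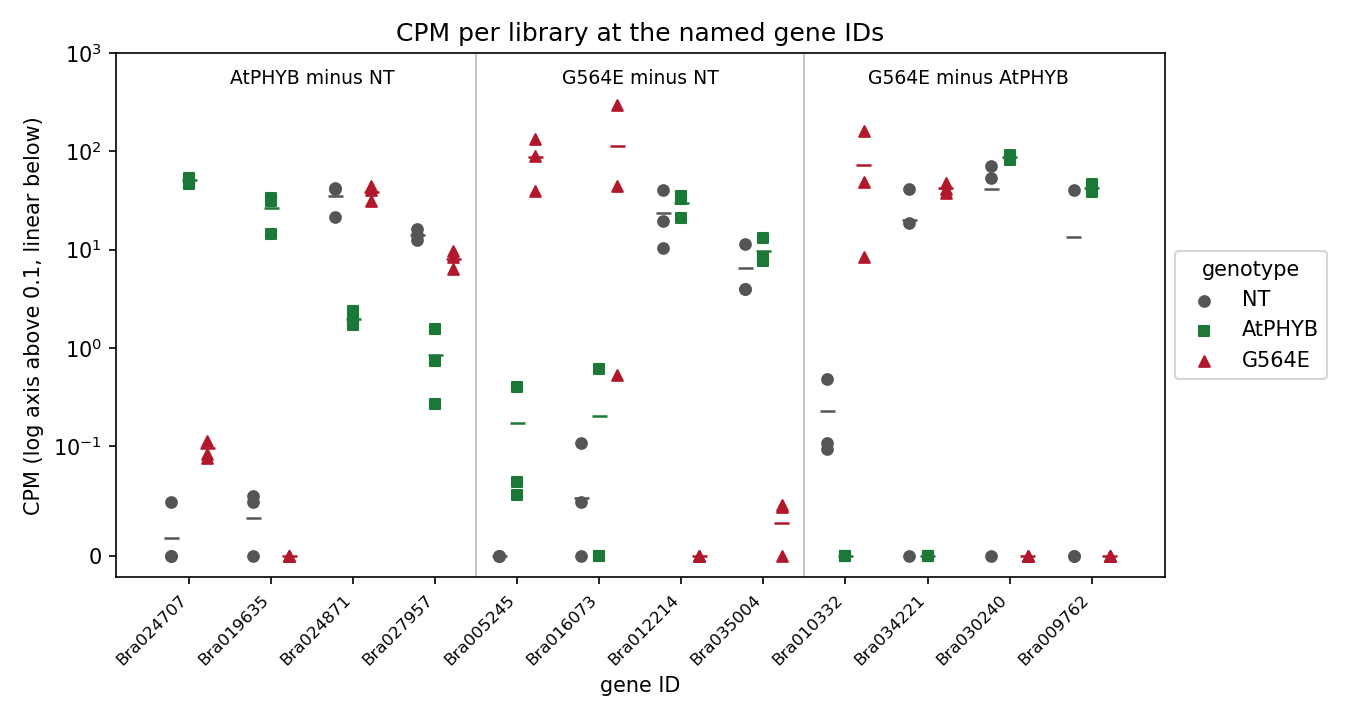
CPM per library at the named gene IDs of each comparison, on an axis that is logarithmic above 0.1 CPM and linear below; points are libraries, coloured by genotype, and short lines are group means (n = 3). Bra024707 and Bra019635 have reads above 10 CPM in AtPHYB libraries alone, and at Bra034221, Bra030240 and Bra009762 the NT libraries include both values of 0 and values above 10 CPM.

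The responses of the transgenic genotypes were then set side by side. Of the 53 genes called in AtPHYB, 22 were also called in G564E against NT: 12 higher in both, 8 lower in both and 2 in opposite directions. Independent lists of these sizes would share 3.99 higher and 3.17 lower genes, and simulated libraries with no effect, in which almost no gene is called, shared 0. Neither value allows for real effects and the common NT libraries together, so part of the excess may come from those libraries. At 42 of the 53 genes G564E differed from AtPHYB in the direct test, against 35.0% of all genes; the 53 genes were chosen with the same AtPHYB libraries, which favours such a difference. Across all genes, which are not independent replicates, the log2 fold changes of the pair of comparisons correlated at 0.03 (Pearson), against 0.51 in simulated libraries with no effect. Effects present in G564E but not in AtPHYB widen the fold changes and lower a Pearson correlation, so these correlations are not a like comparison. The observed correlation was 0.0101 to 0.159 with single libraries left out, the highest without NT replicate 3, and 0.183 without a low-count filter. The covariance was 0.03 against a simulated 0.10, a difference of -0.08. The simulated libraries were drawn independently. If AtPHYB and G564E libraries of the same number are paired, their shared deviations would add 0.0268 to the covariance expected with no effect. In G564E, 3045 genes were called higher and 3072 lower than in NT and in AtPHYB alike, and 6 were called in opposite directions. Independent lists would share 707 and 613 genes, and simulated libraries with no effect, in which almost no gene is called, shared at most 1. Both comparisons use the same G564E libraries, and neither value shows how many shared calls these alone would give.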

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

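Libraries held 15262884 to 20998541 counts. With 200 genes changed in simulated data, 4-fold changes were recovered at 69% to 79% and 2-fold changes at 4% to 14%. Small changes may therefore be missed where few genes are called, as in AtPHYB minus NT. The adjustment is less strict where many genes change, so these shares do not carry over to the G564E comparisons. The lower quartile of the absolute log2 fold change of called genes was 0.765 for G564E minus NT and 0.779 for G564E minus AtPHYB, less than 2-fold. For AtPHYB minus NT, the 53 genes became 6 at an adjusted p under 0.01, 961 in DESeq2 and 199 in a fit of the compared genotypes alone. Leaving out single libraries gave 6 to 783 genes, and all 53 genes were again called without NT replicate 3 and without G564E replicate 1. For G564E minus NT, the 7545 genes became 3170 at an adjusted p under 0.01 and 4453 with a change of at least 2-fold, and 4829 to 10702 with single libraries left out. For G564E minus AtPHYB, the 9777 genes became 4684 and 5917 under those thresholds, and 6063 to 12878 with single libraries left out. The correlation of the responses against NT was 0.183 without a low-count filter and 0.081 in separate fits, and 0.0101 to 0.159 with single libraries left out; the cause was not tested. With the replicate block the counts were 17 for AtPHYB minus NT, 6655 for G564E minus NT and 9045 for G564E minus AtPHYB. The libraries of AtPHYB and NT share only a number, and 6 of the 9 libraries deviated most like one of their own number. A block fit of G564E and AtPHYB alone, added after seeing the data, gave 9251. With the block Bra027957 lost its call in AtPHYB minus NT (edgeR adjusted p = 0.0559), and no other named ID did. Other scalings, filters, limma-voom, a robust prior and the removal of the 56 on/off genes left each total count within 1.5 times. The last 2 of these were chosen after seeing the data. Similar totals did not always hold the same genes. For AtPHYB minus NT, limma-voom called 47 genes, 35 of them among the 53. Library size alone called again 6027 of the 7545 genes and 7606 of the 9777, and moved the split of higher and lower genes. Named IDs kept their direction in all 224 recomputed values and lost their call in 15. They were chosen for large changes without overlap between genotypes, so refits of the same libraries could hardly reverse a direction. DESeq2 gave no adjusted p for Bra009762. Rankings added after seeing the data gave 59 to 76 lower genes among the 100 most abundant for G564E minus NT and 71 to 82 for G564E minus AtPHYB, but 23 and 29 when ranked by G564E alone. Rankings by NT or AtPHYB may favour genes lower in G564E. The 33 gene lists could not be run, because their members could not be identified.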

Other observations

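The on/off genes, the position of NT replicate 3 and the tests of abundant genes with library size alone were examined only after the data had been seen; the tests of depth, G564E replicate 1, neighbouring IDs, transgene reads and other splits were set out before their results.

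Of the 56 on/off genes, 47 differed in state between NT libraries, 7 between AtPHYB libraries and 9 between G564E libraries. At 17 of them NT replicate 3 and the AtPHYB libraries were on while NT replicates 1 and 2 and the G564E libraries were off, and at 11 the states were the other way round. For a mislabelled AtPHYB library a first test at the on/off genes did not separate the options: of 20 genes on in AtPHYB and off in NT replicates 1 and 2, NT replicate 3 was off at 2, and AtPHYB libraries left out in the same way were off at 0 to 2. A second test, chosen after that result and over more genes, did not decide it either. At genes called between AtPHYB libraries and NT replicates 1 and 2, NT replicate 3 lay nearer to NT replicates 1 and 2 at 18.4% to 22.1% of genes, while an AtPHYB library left out of the same call did so at 0.68% to 5.31%. The spread between only 3 left-out libraries puts the upper 95% prediction limit at 14.8% on the percent scale but at 77.9% on the logit scale, so a mislabelled library stays open. NT replicate 3 lay at a median of 0.889 to 0.904 of the way to AtPHYB, and the left-out AtPHYB libraries at 0.977 to 1. At genes called with all AtPHYB libraries, NT replicate 3 lay at a median of 0.813 and nearer to NT replicates 1 and 2 at 24.8% of genes. A candidate explanation is that the seedlings carried different versions of some stretches of the genome, shared by NT replicate 3 with AtPHYB and by NT replicates 1 and 2 with G564E. The prediction that neighbouring on/off IDs share a pattern gave a permutation p = 0.1 but rested on 1 pair of IDs, so this stays open, as does an outside library under the label of NT replicate 3.

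The large response of G564E was weighed against depth, abundant genes and its deviating library. Thinning all libraries to the smallest total left 7370 genes changed against NT, and leaving out G564E replicate 1 raised the count to 10702, against 7545 with all libraries. This argues against depth and against that library as the whole cause. Removing the 100 most abundant genes left 7403 under TMM, which decides nothing, because that scaling already trims such genes. With library size alone the removal took the count from 10012 to 8348, which argues against a few abundant genes as the whole cause of the number but goes with a part in it. With library size alone 78.2% of the genes called against NT were higher, and 67.5% once the 100 most abundant genes were removed. The bound for this test, a fall of more than 10 points, was set after the 78.2% was known and was only just passed, with no spread to judge it by. The genes removed came from the ranking that favours genes lower in G564E. Abundant genes are therefore a candidate explanation for part of that split, removing more than 100 of them was not tried, and how many genes rose or fell depends on the scaling. The labels give no batch. The introduced gene, the plant line and any difference in growth or handling all follow the genotype and stay open, untested. Of the on/off genes, 2 were off in all G564E libraries and on in all others, and 0 were of the reverse kind.

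Transgene reads counted at one gene ID that is silent in non-transgenic plants would give an ID seen in transgenic libraries alone. No ID had 1 CPM or more in all 6 transgenic libraries and 0 reads in NT (0 IDs, against a median of 0 and at most 2 in the 83 other choices of 3 libraries), so such an ID was not seen. This does not bear on reads counted at a resident phytochrome gene that NT also expresses.

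Other splits of the same 6 libraries, 3 against 3, gave at most 1 gene for AtPHYB against NT, where the real split gave 53. They gave 0 for G564E against NT, where the real split gave 7545, and 0 for G564E against AtPHYB, where it gave 9777. In each case 1 of 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. Every other split puts libraries of both genotypes in the same group. Where the genotypes differ this widens the spread within groups, so few calls would follow there in any case, and the low counts decide nothing. For G564E against AtPHYB, libraries of the same number may be paired. The 3 other splits that part all 3 such pairs are among those that gave 0, and they too mix the genotypes.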
